A study of Mus musculus with 6 samples.

How the data were processed

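Total RNA from the uterus of ovariectomized mice was measured on 6 one-colour Affymetrix arrays, 3 after sesame oil and 3 after progesterone. Per the labels' protocols, biotinylated cRNA was made from total RNA extracted with a column kit, and per the series' design text RNA was pooled from 3 mice. The deposited values are log2 expression values of 45101 probe sets, with 2 decimals, and per the submitters' processing notes Partek 6.6 and RMA were used. The authors' background correction and normalization settings beyond these names were not given in the sources used here. The array medians lay between 5.51 and 5.53 and the values between 2.40 and 14.70. Detection calls and scanner files were not used here, so the level of the TrpnX control probe sets, between 2.87 and 3.34, stands for background. Of the genes past the threshold, 8 had a group mean at or below 3.34.

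Gene names came from the platform annotation. Of the probe sets, 64 were controls, 34945 had 1 gene symbol, 932 had several and 9160 had none here. Gene identifiers of 34741 were found in the RefSeq gene table of GRCm38.p6, which was used for names only and changed 0 symbols. For each of 18193 genes, the probe set with the highest mean over the 6 arrays was used. Among called genes, 1281 had several probe sets: in 557 another passed in the same direction, in 3 (Pnkd, Rmdn1 and Numa1) another passed in the opposite direction, and in 722 no other passed. Genes without a match, Areg among them, were not analysed by name here. Their probe sets may be among those with no gene symbol or with several, so they may still have been measured.

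Groups came from the sample labels. The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no filter on dim genes, no block), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. All tests were two-sided. The 24 gene lists and 18 lists of cell type markers were fixed before the data were examined, as were the design and the alternatives. Lists with at least 5 measured genes, 41 in number, were tested with camera (preset correlation 0.01) against all other genes, adjusted over the 41 lists. The erythroid list had too few measured genes to be tested, and none of its members passed: the adjusted p of Alas2, Hba-a1, Hba-a2 and Slc4a1 lay between 0.285 and 0.822. The median and mean of the list differed in sign for steroid receptors, oestrogen-responsive genes, EGF family, BMP, prostaglandins, angiogenesis, circadian clock, B cell, mast cell and skeletal muscle, none of which passed camera. Fry and camera with an estimated correlation were alternatives. Array quality measures were compared by exact permutation over the splits of the 6 arrays, which cannot give a p below 0.1.

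Genes were named by a rule. It took the 12 largest rises and 12 largest falls past the threshold whose arrays lay apart between groups, leaving out clone and model names. It also took up to 4 members of each gene list past the threshold by size of change (where fewer than 2 passed, the member with the largest change), Gata2, Pgr, Ihh, Areg, Il13ra2, Sox17 and Esr1 in any case, and up to 3 members of each marker list that passed. It gave 98 genes, 90 of them past the threshold, and not all of them are printed below. Genes named for the level on single arrays, and those named with the lists added later, were chosen after their values were seen.

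Both groups carry replicate numbers, and nothing in the labels says what a number shares. Deviations from the group means correlated between same-numbered arrays at 0.523, 0.141 and 0.636 across genes, all above 0.1, so by the rule used here the numbers pair the samples. This pairing is a hint from the data. Oil replicate 2 correlated better with progesterone replicate 1 (0.322) than with its own number. The fit with the replicate block had been run before this check was made, and the decision follows a fixed rule. Blocked values are printed where they change a call.

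The procedure was tested on simulated data with 18193 genes and 50 changed genes per size. For 3 arrays against 3 it recovered 3 of 50 genes changed by 0.5 on the log2 scale and 35 of 50 changed by 1. It recovered 49 of 50 changed by 2 and 50 of 50 changed by 3, with 4 false among 141 calls. The simulated genes varied independently of each other and few were changed, while 2137 genes were called in the real data. These rates therefore need not hold in the real data. The alternatives were renormalization by quantiles, centring on array medians, an offset of 32 before log2, leaving out the lowest 25% or 50% of genes by level, the mean of a gene's probe sets, every probe set on its own, trended and robust eBayes, an unmoderated linear model, the replicate block, each array left out, an adjusted p of 0.01 and a minimum of 1.5-fold. Chosen after seeing the data were the fits without the arrays in doubt and with S100a8 and S100a9 as a covariate. To place a list's median on 1 array, 10000 random lists of the same size matched on mean level were drawn. Python 3.11.15 with numpy 2.4.6 and matplotlib 3.10.9 drew the plots.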

Results

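Gene expression was measured in the whole uterus of ovariectomized mice that carried the floxed Gata2 allele (f/f). No recombinase is named in the sample descriptions. The uterus without ovaries receives little ovarian steroid, so a single injection shows the early response to a hormone. Ovaries were removed at 6 weeks of age, and at 8 weeks the mice received sesame oil or 1 mg of progesterone in 100 µl of oil, and the tissue was taken 6 h later. Each group had 3 arrays, and the RNA was described as pooled from 3 mice. Whether each array held a separate pool was not stated, so the p-values measure the spread between these samples, which may be partly technical. The comparison addressed which transcripts respond to progesterone within 6 h. Levels are log2 values from RMA, a method that combines the probes of a probe set after background correction and quantile normalization, and the number of arrays limits their precision.

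Of 18193 genes tested, 1077 were higher and 1060 were lower after progesterone (limma, Benjamini-Hochberg adjusted p under 0.05). Pate4, which encodes a small secreted protein, showed the largest rise, from 2.93 ± 0.0839 to 7.82 ± 0.353 (log2, mean ± SD, n = 3 per group). Its oil level was no higher than that of the TrpnX control probe sets, which have no mouse target and reached 3.34, so its 29.5-fold difference was measured against background. Lrp2, the endocytic receptor megalin, was 22.6-fold higher (log2 change 4.50 ± 0.267 SE, limma adjusted p = 0.0011), and Npl, a lyase of sialic acid catabolism, was 14.8-fold higher. Il13ra2, the decoy receptor for interleukin 13, rose 13.0-fold, and Cyp26a1, a hydroxylase that clears retinoic acid, rose 12.8-fold. The other genes among the 12 largest rises, ranked in the same way over named genes, were Fam107a (12.5-fold), Map7d2 (log2 change 3.58), Spink8 (10.2-fold), Hsd11b2 (9.13-fold), Acot7 (8.59-fold), Fkbp5 (7.89-fold) and Cwh43 (7.41-fold). Hsd11b2 inactivates corticosterone, and Fkbp5 is a co-chaperone of steroid receptors. The limma adjusted p of these genes lay at or below 0.0146. The call of Cwh43 ended without oil replicate 1 (adjusted p = 0.0527) and also without progesterone replicate 2.

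The largest fall was that of Gabrp, the pi subunit of the GABA-A receptor, from 8.87 ± 0.516 to 5.79 ± 1.15 (log2, mean ± SD, n = 3 per group), or 8.46-fold. Its log2 change was -3.08, and -3.70 without progesterone replicate 3. Speer4cos was 5.79-fold lower, Ctnnd2, a delta-catenin, 5.70-fold lower, and Abca4, a retinoid transporter, 5.21-fold lower. Sv2b (4.96-fold), Capsl (4.29-fold), Wnt7a (4.28-fold), Pik3ip1 (4.26-fold), Cdkl1 (4.17-fold), Aldh1a3 (4.0-fold), Acpp (3.80-fold) and Sema3e (3.75-fold) completed the 12 largest falls among genes with a name of their own, since probe sets without a single gene name were not ranked. Wnt7a is a Wnt ligand of the uterine epithelium, Pik3ip1 an inhibitor of phosphatidylinositol 3-kinase and Aldh1a3 an enzyme that makes retinoic acid. By the rule that chose them, all 24 of these genes had the 3 progesterone arrays to one side of the 3 oil arrays. Ctnnd2, Wnt7a and Acpp have other probe sets, none of which passed. Without oil replicate 2 the calls of Gabrp (adjusted p = 0.0628), Aldh1a3 (0.05) and Sema3e (0.146) ended, and that of Sema3e also ended without oil replicate 1, progesterone replicate 2 or progesterone replicate 3.

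**Figure D1:**
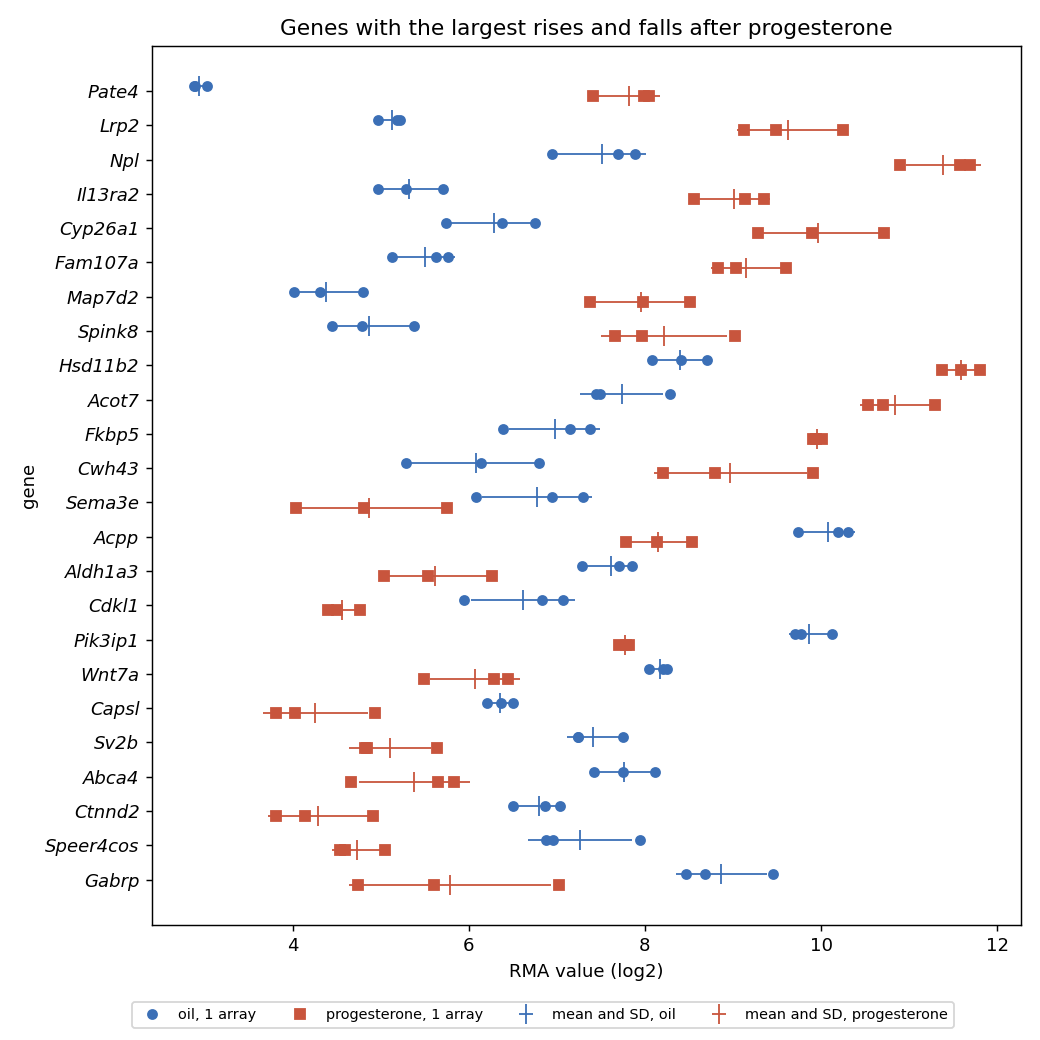
RMA values (log2, horizontal axis) of the 12 genes with the largest rises and the 12 with the largest falls (vertical axis), with circles for the 3 oil arrays, squares for the 3 progesterone arrays, and a tick and line for the mean and SD of each group. Lrp2 lay near 5.12 on average on the oil arrays and 9.62 on the progesterone arrays. Only genes whose groups did not overlap were chosen.

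The counts of changed genes fell when any 1 array was left out, and fewer arrays alone lower the power to call genes. The size of the fall differed between arrays. Without oil replicate 1, 457 genes were higher and 443 lower, and without oil replicate 2 there were 379 and 278. Without progesterone replicate 2 there were 499 and 500. The count of lower genes was 697 without oil replicate 3 and 626 without progesterone replicate 3. Over all genes, the arrays of the groups lay apart for 5522 genes, or 30.4%, where chance gives 10%. A change of at least 1.5-fold was seen in 674 of the higher and 642 of the lower genes. An unadjusted p under 0.05 in limma was seen in 4730 genes. The counts of list members below are to be read beside 1077 higher and 1060 lower among all 18193 genes.

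The list of acute progesterone targets of the uterus had the highest share of higher genes among the 24 gene lists fixed before the data were examined. Of its 22 measured members 13 were higher, 1 was lower and 8 did not pass (14 higher and 1 lower adjusted over the list alone), and the median log2 change was 1.86. Beside Lrp2, Il13ra2, Cyp26a1 and Hsd11b2, Ihh, the hedgehog ligand of the uterine epithelium, rose 4.09-fold (log2 change 2.03 ± 0.262 SE, limma adjusted p = 0.00605). The list stood above the other genes in camera with a preset correlation of 0.01 (adjusted p = 2.18e-10), but not with an estimated correlation (adjusted p = 0.202). It was written from general knowledge of this organ, which can include work on these very animals, and is not independent evidence of direction. None of the 41 lists tested passed with an estimated correlation. Camera has fewer degrees of freedom when it estimates the correlation from so few arrays, so a lost call need not come from correlation between genes. The cell cycle inhibitors, with an estimated correlation of -0.0334, went from an unadjusted camera p of 0.0124 at the preset correlation to 0.0539.

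In the glucocorticoid-type steroid response, 9 of 22 measured members were higher, 1 was lower and 12 did not pass (10 and 2 adjusted over the list alone). The list passed camera as higher with the preset correlation (adjusted p = 0.000134) and not with an estimated correlation (adjusted p = 0.618). Sgk1, a kinase that controls sodium channels, was 7.21-fold higher, and the transcription factor Zbtb16 5.79-fold higher. Pdk4, a kinase that restrains pyruvate dehydrogenase, fell 3.47-fold (log2 change -1.79 ± 0.112 SE, limma adjusted p = 0.0011). It shares Fkbp5, Sgk1, Zbtb16, Tsc22d3, Per1, Klf9, Errfi1 and Cebpb with the progesterone targets, so the lists are not independent.

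Of the 25 measured genes of the heat shock and unfolded protein response, 9 were higher, 0 lower and 16 not past the threshold (15 higher adjusted over the list alone). Sdf2l1, Manf and Creld2, which act in the endoplasmic reticulum, were 3.12-fold, 2.70-fold and 2.61-fold higher, and Asns, asparagine synthetase, was 3.05-fold higher (log2 change 1.61 ± 0.112 SE, limma adjusted p = 0.0011). Camera with the preset correlation gave an adjusted p of 2.07e-07, and the adjusted p was 0.618 with an estimated correlation.

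**Figure D2:**
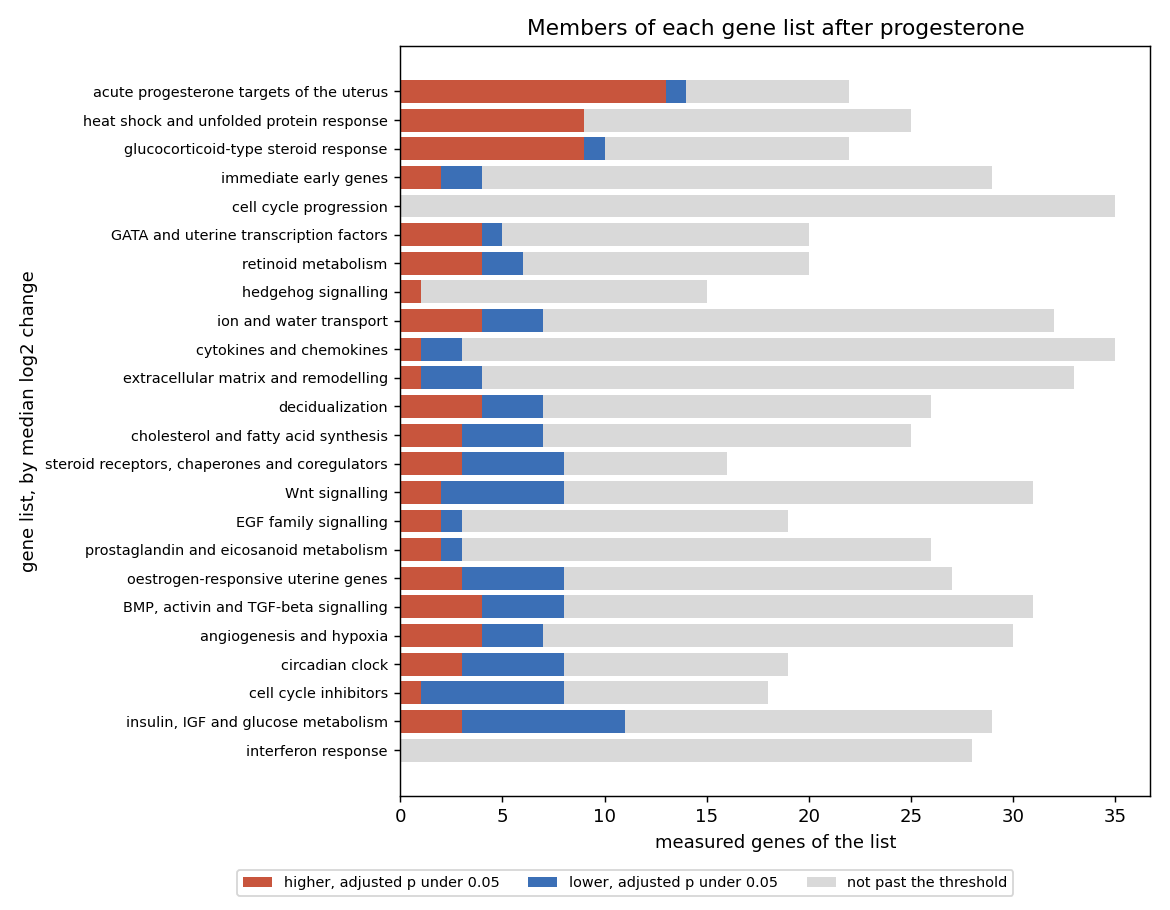
Measured genes of each of the 24 gene lists (horizontal axis, number of genes), ordered by the median log2 change (vertical axis), split into genes higher, lower and not past the threshold after progesterone. The progesterone targets had 13 higher and 1 lower of 22, and the cell cycle progression list had 0 of 35 past the threshold.

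Among the steroid receptors, chaperones and coregulators, 3 of 16 measured genes were higher and 5 lower, with 8 not past the threshold (4 and 5 adjusted over the list alone). The progesterone receptor Pgr fell by 1.06 on the log2 scale, from 11.48 to 10.42 (2.08-fold lower, SE 0.102, limma adjusted p = 0.00255). The oestrogen receptor Esr1 was 1.37-fold lower (adjusted p = 0.0243), and the chaperone Hsp90aa1 was 1.60-fold higher. Gata2 itself was 1.69-fold higher (log2 10.34 to 11.10, SE 0.184, limma adjusted p = 0.0411). Of the 20 measured GATA and uterine transcription factors 4 were higher, 1 was lower and 15 did not pass (6 and 1 adjusted over the list alone). Hoxa11 and Hoxa10, homeobox factors of the stroma, rose 2.18-fold and 1.84-fold, and Hand2, a stromal factor, rose 1.55-fold. Pgr, Esr1, Hoxa10 and Hand2 each had several probe sets, of which only the 1 used passed. Sox17 was at 11.37 with oil and 11.95 with progesterone (adjusted p = 0.0982), and its adjusted p with the replicate block was 0.0466. The calls of Gata2 and Esr1 ended without oil replicate 2 (adjusted p = 0.132 and 0.0953) and without oil replicate 1, oil replicate 3, progesterone replicate 2 or progesterone replicate 3. That of Hand2 ended without oil replicate 1 or oil replicate 2, and that of Hsp90aa1 without oil replicate 2, progesterone replicate 1 or progesterone replicate 2.

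In insulin, IGF and glucose metabolism, 3 of 29 measured genes were higher and 8 lower, with 18 not past the threshold (4 and 13 adjusted over the list alone). Pfkfb3, which drives glycolysis, rose 6.05-fold, the glucose transporter Slc2a3 3.85-fold and Igf1 3.94-fold, while the median of the list was -0.31. The list passed camera as lower with the preset correlation (adjusted p = 0.0446), and its adjusted p was 0.845 with an estimated correlation. Its call also ended without oil replicate 2, oil replicate 3, progesterone replicate 1 or progesterone replicate 3 (adjusted p between 0.0638 and 0.101). It ended without the lowest 25% or 50% of genes by level (adjusted p = 0.121 and 0.206) and with the mean of probe sets (0.0676), as well as without oil replicate 3 and progesterone replicate 3 together (0.16) and without the 3 arrays with S100a8 above 11 (0.131). Its counts were 5 higher and 9 lower with the replicate block. Among 18 cell cycle inhibitors, 1 was higher and 7 were lower (3 and 8 adjusted over the list alone). Ccng1 was 2.46-fold higher, and Gadd45a, Ccng2 and Btg1 were 2.22-fold, 1.71-fold and 1.63-fold lower, with a list adjusted p of 0.0637, and with the replicate block 2 were higher and 7 lower. The call of Gadd45a ended without oil replicate 2 (adjusted p = 0.0512). Of the probe sets of Btg1 only the 1 used passed. None of the 35 measured cell cycle progression genes passed in limma, and adjusted over the list alone the count was 0 as well. An unadjusted p under 0.05 in limma was seen in 5 of them, a lower share than the 4730 of 18193 over all genes. With the replicate block Ccne2 was higher and Mcm6, Mcm7 and Bub1b were lower, named after their values were seen, and the camera adjusted p of the list was 0.382. These genes varied within the groups: their median was 0.65 higher on oil replicate 3 than on the other oil arrays and 0.62 higher on progesterone replicate 3 than on the other progesterone arrays. Ube2c had an SD of 1.48 with oil and 1.24 with progesterone (adjusted p = 0.544, and 0.0628 with the replicate block).

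In retinoid metabolism 4 of 20 measured genes were higher and 2 lower (6 and 4 adjusted over the list alone). Beside Lrp2 and Cyp26a1, the retinol carrier Ttr was 6.09-fold higher, and Aldh1a3 was lower. Ttr is also abundant in liver. It was 5.61, 4.81 and 7.44 on oil replicates 1 to 3, and the liver transcript Alb was 4.29, 4.16 and 8.71 on the same arrays. Of the fits without 1 array, only that without oil replicate 3 kept the call of Ttr, with a log2 change of 3.35 against 2.61 over all arrays. In the circadian clock list 3 of 19 were higher and 5 lower (4 and 7 adjusted over the list alone): Nfil3 and Npas2 rose 4.16-fold and 3.94-fold, and Rora and Per3 fell 2.06-fold and 2.07-fold. Of 32 ion and water transport genes 4 were higher and 3 lower (6 and 3 adjusted over the list alone), among them the sodium pump subunit Atp1b1, 4.45-fold higher. Of 25 cholesterol and fatty acid synthesis genes 3 were higher and 4 lower (6 and 4 adjusted over the list alone). Acaca was 2.38-fold and Dhcr7 1.77-fold higher, and Stard4 was 1.79-fold and Scd1 1.58-fold lower. The call of Stard4 held in 5 of the 6 fits without 1 array and that of Scd1 in 1. Of 26 prostaglandin and eicosanoid genes 2 were higher and 1 lower (3 and 1 adjusted over the list alone), with the prostaglandin receptor Ptger3 3.20-fold higher. Only 1 of several probe sets passed for Npas2, Stard4, Scd1 and Ptger3. Of 30 angiogenesis and hypoxia genes 4 were higher and 3 lower (5 and 4 adjusted over the list alone), including placental growth factor, Pgf, 2.69-fold higher. With the replicate block 7 and 3 ion and water transport genes were higher and lower, as were 5 and 4 of cholesterol and fatty acid synthesis, 3 and 2 prostaglandin genes and 6 and 5 angiogenesis genes. None of these lists passed camera.

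Among the signalling lists, hedgehog had 1 of 15 members higher, which was Ihh, and 0 lower (1 and 0 adjusted over the list alone). In Wnt signalling 2 of 31 were higher and 6 lower (2 and 7 adjusted over the list alone), with Fzd1 1.93-fold higher and Fzd10 2.07-fold lower. Beside Wnt7a, Lgr5 was 3.20-fold lower, a call that held in 1 of the 6 fits without 1 array. In BMP, activin and TGF-beta signalling 4 of 31 were higher and 4 lower (4 and 5 adjusted over the list alone). Follistatin, Fst, was 6.95-fold higher and Fstl3 2.35-fold higher, and the call of Fst ended without oil replicate 1, oil replicate 2, progesterone replicate 2 or progesterone replicate 3 (adjusted p up to 0.0889). Inhbb and Inhba were 1.93-fold and 1.59-fold lower, and their calls held in 0 and 1 of the 6 fits without 1 array. In EGF family signalling 2 of 19 were higher and 1 lower (2 and 2 adjusted over the list alone), with Errfi1 2.59-fold and Egfr 1.99-fold higher. Spry1 was 1.67-fold lower, and its call held in 1 of the 6 fits without 1 array. The oestrogen-responsive list had 3 of 27 higher and 5 lower (3 and 5 adjusted over the list alone), with Greb1 3.23-fold higher. Beside Wnt7a, Padi1 was 2.54-fold lower, and its call held in 3 of the 6 fits without 1 array. Decidualization had 4 of 26 higher and 3 lower (4 and 3 adjusted over the list alone). Alpl, Hoxa11 and Hoxa10 were 3.57-fold, 2.18-fold and 1.84-fold higher, and Lifr was 2.46-fold lower. The call of Alpl ended without oil replicate 1 or oil replicate 2. The extracellular matrix list had 1 of 33 higher and 3 lower (1 and 3 adjusted over the list alone), with Mmp11 2.45-fold and Mmp10 2.05-fold lower. Immediate early genes had 2 of 29 higher and 2 lower (5 and 3 adjusted over the list alone), with Nr4a3 2.91-fold higher. Only 1 of several probe sets passed for Fzd10, Lgr5, Inhbb, Inhba, Lifr and Nr4a3. With the replicate block the counts of higher and lower members were 6 and 6 in the oestrogen-responsive list, 3 and 2 in EGF family signalling, 3 and 3 in the extracellular matrix list and 5 and 3 among immediate early genes. None of these lists passed camera.

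Immune transcripts varied between arrays of one group. Of 35 cytokines and chemokines 1 was higher, which was Il6, and 2 were lower (1 and 1 adjusted over the list alone), and with the replicate block 3 were higher and 3 lower. Il6 went from 3.19, within the range of the TrpnX control probe sets, to 4.82, and its call ended without oil replicate 2 (adjusted p = 0.0523). None of 28 interferon response genes passed on its own in limma, also adjusted over the list alone. The share with an unadjusted p under 0.05 in limma, 5 of 28, was below that of all genes (4730 of 18193). Of the 28, 11 were lower and 0 higher with the replicate block. The interferon list as a whole was lower in camera with the preset correlation (adjusted p = 0.0451), which ended with an estimated correlation (adjusted p = 0.996) and without oil replicate 2, oil replicate 3, progesterone replicate 1 or progesterone replicate 2 (adjusted p between 0.061 and 0.71). The interferon call also ended after renormalization by quantiles (adjusted p = 0.0581), with 32 added before log2 (0.0763), without the lowest 25% or 50% of genes by level (0.0901 and 0.0736), with the mean of probe sets (0.0678) and in fry (0.756). It held without oil replicate 1 (adjusted p = 3.06e-05), progesterone replicate 3 (0.000108), both oil replicate 3 and progesterone replicate 3 (0.00908) or the 3 arrays with S100a8 above 11 (0.0011). It also held with centring (0.0339), with trended and robust eBayes (0.0381) and with the replicate block (1.38e-05, and adjusted p = 0.882 with an estimated correlation). Ifit3 was at 7.25, 8.15 and 8.57 on oil replicates 1 to 3 and at 6.30, 6.68 and 7.62 on progesterone replicates 1 to 3 (adjusted p = 0.143), with an adjusted p of 0.00541 under the replicate block. S100a8 was 4.92, 4.34 and 11.82 on oil replicates 1 to 3 and 5.01, 12.02 and 12.48 on progesterone replicates 1 to 3. Cxcl5 was 11.27 on oil replicate 3 and 10.88 on progesterone replicate 3, and no higher than 3.89 on the other 4 arrays.

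**Figure D3:**
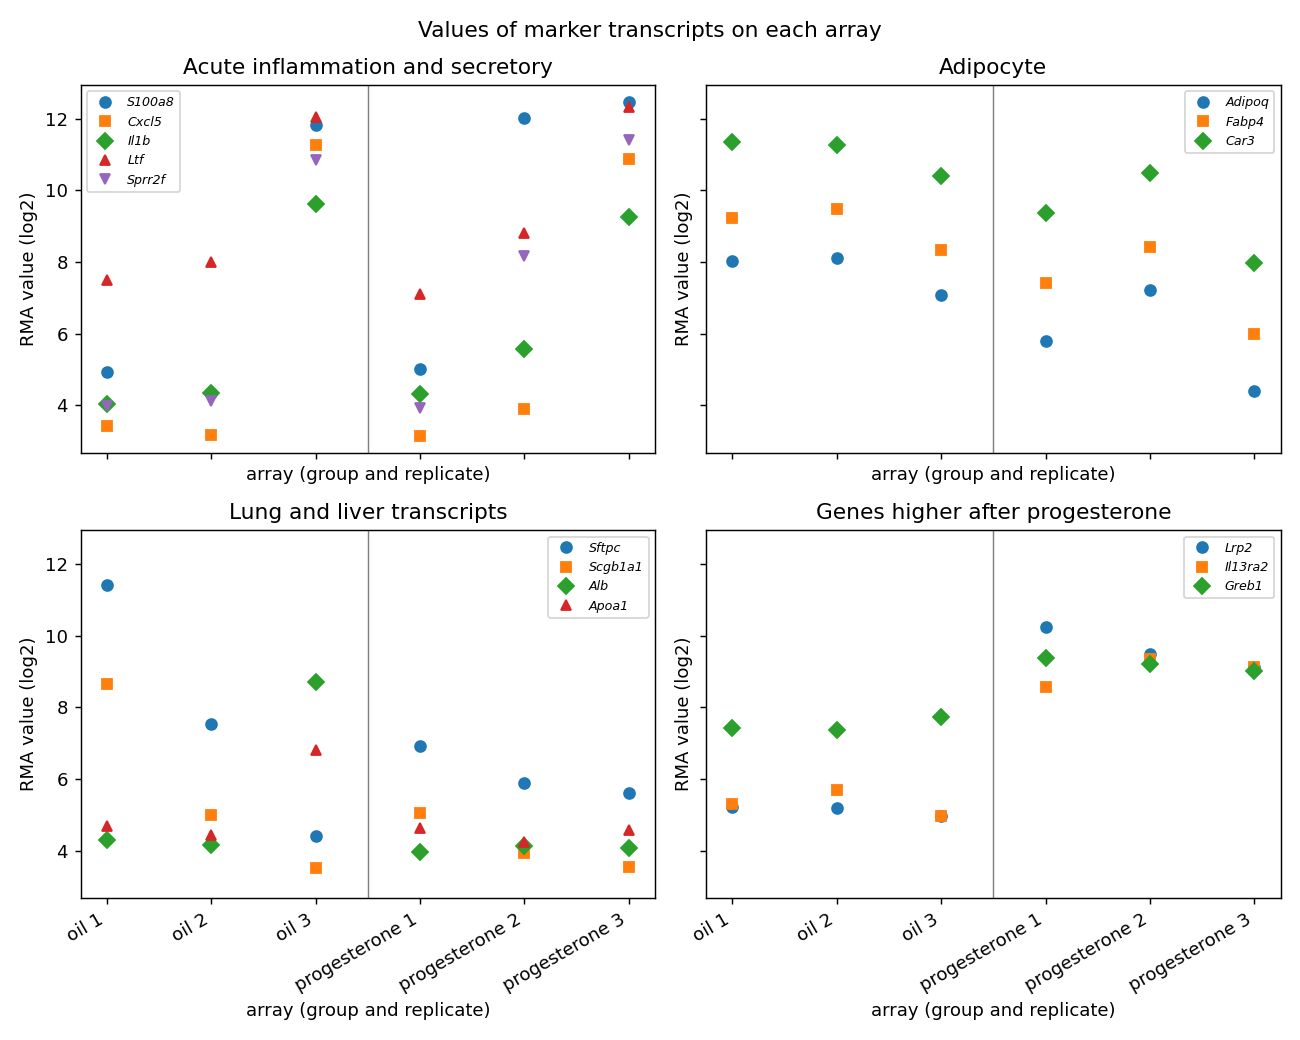
RMA values (log2, vertical axis) of marker transcripts on each of the 6 arrays (horizontal axis), with a grey line between the oil and progesterone arrays and 1 symbol per gene. S100a8 was high on oil replicate 3 (11.82) and on progesterone replicates 2 and 3 (12.02 and 12.48), Sftpc on oil replicate 1 (11.41) and Alb on oil replicate 3 (8.71), while Lrp2 was high on the 3 progesterone arrays.

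Markers of other cell types in the tissue were tested in the same way. Adipocyte markers had 0 of 10 past the threshold over all genes in limma (7 at an unadjusted p under 0.05), 7 lower adjusted over the list alone and 6 lower with the replicate block, and the list was lower in camera with the preset correlation (adjusted p = 0.00627, and adjusted p = 0.845 with an estimated correlation). In fry its adjusted p was 0.103. Adipoq was 8.02, 8.11 and 7.08 on the oil arrays and 5.80, 7.21 and 4.39 on the progesterone arrays (adjusted p = 0.113). With the replicate block, the adjusted p of Adipoq, Fabp4 and Car3 was 0.0135, 0.00765 and 0.0143. Without progesterone replicate 2 that of Adipoq and Car3 was 0.0399 and 0.0482. Endothelial markers had 1 of 12 lower, which was Cldn5 at 1.88-fold (1 adjusted over the list alone, and 3 lower with the replicate block), and the list was lower in camera (adjusted p = 0.00916, and adjusted p = 0.848 with an estimated correlation). The call of the endothelial list ended without oil replicate 2 (adjusted p = 0.0517), in fry (0.171), without oil replicate 3 and progesterone replicate 3 together (0.0894) and without the 3 arrays with S100a8 above 11 (0.103), and that of Cldn5 ended without each progesterone array. Tek and Pecam1 had adjusted p of 0.0707 and 0.115, and of 0.0352 and 0.0293 with the replicate block, and that of Tek was 0.0432 without oil replicate 1. Among 14 endometrial stroma markers 3 were higher and 1 lower, among 19 epithelial markers 1 was higher and 1 lower (1 and 2 adjusted over the list alone), and among 9 gland markers 1 was higher. The epithelial markers varied between the progesterone arrays. Their median on progesterone replicate 2 differed from the other progesterone arrays by -0.525, with 10 members over 0.5 lower. It was 0.285 and 0.255 higher on progesterone replicates 1 and 3. Whether the share of epithelium affected the size of the named falls was not tested. Among 9 mast cell and 9 skeletal muscle markers 1 of each was higher, and among 6 markers of nerve and glia 1 was lower. No marker passed over all genes among those of smooth muscle (14 measured), lymphatic endothelium (5), macrophages (13), T and NK cells (11), B cells (7), neutrophils (9), eosinophils (5), mesothelium (8) and oviduct and ovary (7, of which 2 were lower adjusted over the list alone). With the replicate block 2 markers each were lower for epithelium, stroma, and nerve and glia, 1 each for lymphatic endothelium and B cells, and 1 each was higher for macrophages and neutrophils. No marker list other than those of adipocytes and endothelium passed camera.

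Array quality measures were compared by exact permutation. The 3' minus 5' difference of Actb, a measure of RNA degradation, was 1.08 ± 0.101 with oil and 1.15 ± 0.34 with progesterone (log2, mean ± SD, n = 3, exact two-sided permutation p = 0.9). That of Gapdh was 0.547 ± 0.134 and 0.700 ± 0.259 (exact permutation p = 0.6). The 18S rRNA was at 10.15 ± 0.146 with oil and 10.79 ± 0.690 with progesterone (exact permutation p = 0.3), with 10.03, 10.95 and 11.38 on progesterone replicates 1 to 3. The hybridization spike-ins were at 10.50 with oil and 10.33 with progesterone (exact permutation p = 0.1), so the groups did not overlap in this measure, and 0.1 is the smallest p that 3 arrays against 3 allow.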

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

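Probe sets without a single gene name took no part in the comparison of genes. Fitted together with all other probe sets, 497 of 10092 such probe sets passed the threshold between progesterone and oil, 169 of them higher and 328 lower. The largest rise among them was 4.03 on the log2 scale. It was measured against background, since the oil values of 3.54, 3.17 and 2.94 lay near the highest TrpnX value (3.34). The largest falls were -3.04 and -3.01, beyond those of the 12 falls named in the comparison of genes except Gabrp (-3.08). This signal lies in data that the comparison of genes did not use, and was not pursued further.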

How the results depend on the processing

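The fits without oil replicate 3 and progesterone replicate 3, without the 3 arrays with S100a8 above 11, and with S100a8 and S100a9 as a covariate were chosen after seeing the data. Leaving out 1 array gave between 379 and 848 higher genes, between 278 and 907 lower genes, and between 4 and 7 lists past the threshold. The counts of higher and lower genes were 1808 and 1692 with every probe set on its own, where more features are tested, 348 and 245 in the unmoderated linear model, 328 and 243 at an adjusted p under 0.01, and 674 and 642 with at least 1.5-fold. They were 586 and 441 without oil replicate 3 and progesterone replicate 3, and 0 and 0 (1735 and 1644 at an unadjusted p under 0.05 in limma) without the 3 arrays with S100a8 above 11, which leaves 2 oil arrays and 1 progesterone array, the lone array being assumed to vary like the others. The covariate gave 1117 and 1066. Of 41 lists, 7 passed, and 0 with an estimated correlation. The number was 5 without the lowest 25% or 50% of genes by level and with the mean of probe sets, 6 after renormalization by quantiles and without the arrays in doubt, 7 with centring, the offset or the block, and 8 with trended eBayes. Fry, which does not compare a list with other genes, passed 8 lists: it ended the calls of interferon response (adjusted p = 0.756), endothelium (0.171) and adipocyte (0.103), and passed GATA and uterine transcription factors (0.0483), retinoid metabolism (0.0483), cell cycle inhibitors (0.0168) and nerve and glia (0.0483), which camera did not. Apart from fewer arrays or other features, the cause was not tested. The replicate block gave 1382 and 1545 genes, and beside the 7 named genes printed with it, it changed no other call of a named gene and no camera call of a list, while the counts of members that it moved by over 1.5 times stand beside the lists. None of the 98 named genes reversed in an alternative in which it was tested. Every probe set on its own and, for some genes, the filters by level were not among these. For the 90 called genes, leaving out arrays could not reverse the direction, since their groups lay apart on all 6 arrays. Of these 90, 58 stayed past the threshold in all 6 fits without an array. Signal over background limits genes near 3.34. This level comes from the TrpnX probe sets alone, and the background of other probe sets may be higher, which was not tested. Fold changes of genes with 1 low group mean may therefore be limited too. Examples are Capsl (4.25 with progesterone), Ctnnd2 (4.29 with progesterone) and Map7d2 (4.37 with oil).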

Other observations

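The lists in this part were written after the most changed genes had been seen. The tests on single arrays, on the splits of the arrays and on the FoxO targets were chosen after the result was seen, while those on the other 4 added lists were fixed before the remaining members were tested. Ribosome biogenesis genes were higher after progesterone in 49 of 71 measured members and lower in 0 (median log2 change 0.61). The 18S rRNA was at 10.15 ± 0.146 with oil and 10.79 ± 0.690 with progesterone (log2, mean ± SD, n = 3, exact permutation p = 0.3). It is an array quality measure here and was not tested as a measure of ribosome output. Rrp12, Bysl, Pno1 and Rrs1, which act in the making of the ribosomal subunits, were 3.69-fold, 2.80-fold, 2.49-fold and 2.47-fold higher. Members outside the 350 most changed genes in each direction, 52 in number, stood above other genes in camera (unadjusted p = 6.03e-22 with the preset correlation and 0.0172 with an estimated one). Cytosolic aminoacyl-tRNA synthetases were higher in 12 of 19, with Gars 2.19-fold and Aars 2.18-fold higher, and the 16 remaining members gave an unadjusted camera p of 2.81e-08 (0.0131 with an estimated correlation). Serine, one-carbon and nucleotide synthesis genes were higher in 13 of 28, led by the mitochondrial folate enzyme Mthfd2 (7.19-fold), Mthfd1 (2.93-fold), Ctps (2.84-fold) and Phgdh (2.51-fold), and the 23 remaining members gave an unadjusted camera p of 1.29e-07 (0.0288 with an estimated correlation). Adjusted together with the 41 lists fixed beforehand, the p with an estimated correlation was 0.263, 0.263 and 0.281, so these lists did not pass on that scale either, and the unadjusted p of the progesterone targets was 0.00494. A hypothesis consistent with the tests at the preset correlation is that transcripts for making ribosomes, charged tRNA and nucleotides rise as groups within 6 h of progesterone.

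FoxO targets were lower in 22 of 37 measured members and higher in 2 (median -0.58), with Pik3ip1, Pdk4, Irs2 and Ppargc1a 4.26-fold, 3.47-fold, 2.76-fold and 2.61-fold lower. The list shares Pdk4, Irs2, Insr, Igfbp1, Ppargc1a, Foxo1 and Foxo3 with insulin, IGF and glucose metabolism. It also shares Cdkn1b, Gadd45a and Ccng2 with the cell cycle inhibitors, so these lists are not independent. Many members had been seen before the list was tested. With only the most changed genes set aside, 22 members gave a camera p of 0.0036. With the members whose values had been displayed also set aside, 16 remained, and 4 of these were lower and 2 higher. Their camera p was 0.158. The second exclusion was made after the first p was known. Setting aside called genes weakens the test, so whether FoxO targets fall as a group beyond the members that drew attention stays open. Motile cilia genes, to which Capsl belongs, were tested as lower and did not pass as a group. Of 34 measured members 2 were lower. The camera p of the 33 remaining members was 0.235. With oil, 21 of the 34 lay at most 1 above the highest TrpnX value (log2) and 7 lay at or below it, so most had little room to fall. This limit was set after the result was seen, and it leaves open whether such genes fell, against the bound fixed earlier.

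The split of the arrays by treatment called 2137 genes, and of the 10 splits of the 6 arrays into 3 and 3 this was the 1 with as many, the highest other calling 4. Among the 4 splits that part all 3 same-numbered pairs, the other 3 called 0. With 10 splits a share under 0.05 cannot be reached.

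S100a8, Cxcl5 (11.27) and Il1b (9.63) were high on oil replicate 3. That this array held a progesterone sample is argued against by the progesterone targets, whose median on it differed from that of the other oil arrays by -0.0275, and by Lrp2, which was 4.97 there and at least 9.12 on the progesterone arrays. Neutrophils in the tissue are a candidate explanation, though the rise was not particular to their markers. The 7 neutrophil markers other than S100a8 and S100a9 had a median 1.07 higher on oil replicate 3 than on the other oil arrays. This was percentile 100 of random lists, which do not model genes that vary together. Csf3r was at 6.97 there against 4.08 and 4.70. Against their own group these 7 markers lay 1.22 higher on progesterone replicate 2. On progesterone replicate 3 they lay 0.325 higher, with 3 members over 0.5 higher and 3 over 0.5 lower. The 13 macrophage markers lay 1.11 higher on oil replicate 3, at percentile 100. They lay 0.78 and 0.915 higher on progesterone replicates 2 and 3, also at percentile 100. Cytokines, interferon response and cell cycle progression were at percentile 100 on oil replicate 3 as well. An oestrogen-like state stays open. On oil replicate 3 the oestrogen-responsive list lay at percentile 89.3 with 8 members over 0.5 higher and 1 over 0.5 lower. On progesterone replicate 3 it lay at percentile 100 (median 0.26 higher) with 9 and 1. Of its members, Ltf was 12.06 on oil replicate 3 against 7.50 and 8.01 on the other oil arrays. Sprr2f was 10.84 there against 3.98 and 4.11, Lcn2 12.07 against 8.27 and 8.23, and Muc1 9.80 against 7.96 and 8.02. Other members moved little there: Igf1 was 10.28 against 10.35 and 10.25, Greb1 7.72 against 7.43 and 7.37, and Padi1 6.84 against 6.84 and 6.76. No biological explanation named by the design separates arrays of 1 group.

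Sftpc was 11.41 on oil replicate 1, 7.55 on oil replicate 2, 6.93 on progesterone replicate 1 and between 4.41 and 5.89 on the others. Alb was 8.71 on oil replicate 3 and 4.29 or lower on the other 5 arrays. The 9 lung transcripts other than Sftpc, Scgb1a1 and Sftpa1 lay at percentile 99.99 on oil replicate 1 (median 0.33 higher than on the other oil arrays), with Sftpb at 6.06 against 5.61 and 5.27. On progesterone replicates 1 to 3 Sftpb was 5.82, 5.56 and 5.72, so its level on oil replicate 1 stood out little. The 11 liver transcripts other than Alb, Serpina1c, Mup3 and Fabp1 lay at percentile 100 on oil replicate 3 (median 1.17 higher), with Apoa1 at 6.82 and Apoa2 at 6.72. Traces of lung and liver RNA in these samples are a candidate explanation. How many of these transcripts the uterus also expresses was not tested, and no biological explanation was tested.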
